A study of Mus musculus with 4 samples.

How the data were processed

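Total RNA of 3T3-L1 cells was extracted with TRIzol and made into sequencing libraries by Illumina's protocols, per the labels' protocols. The 4 libraries formed 2 groups of 2 biological replicates, Nutlin-3a and DMSO, taken from the sample labels. TopHat2 2.0.11 and the mouse genome build mm10 are named per the submitters' processing notes. The quantifier, its annotation, the selection of messenger RNA, the way the replicates of a group were combined and whether both groups were quantified with the same settings are not given in the sources used here.

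The authors' deposited table listed 24746 transcripts of 16560 gene models with FPKM values (fragments per kilobase of transcript, scaled to the mapped fragments). It held 1 FPKM value per transcript and group and none per library. No transcript was listed at 0 in both groups. The group columns carried the prefixes NUT and DSM, per the file headers; NUT was read as Nutlin-3a, and DSM as DMSO, which was the only other group. A further pair of deposited columns, headed as fold expression, held log2 of the FPKM of the same group and row. They deviated from log2 of the FPKM by at most 0.0067 in Nutlin-3a and 0.0071 in DMSO, so they are no fold change between groups, and they were not used further. The RefSeq accession column was not used, because only 1586 of 22706 accessions found in the reference belonged to the gene symbol of their row. Symbols and positions did match: 15873 of 15900 symbols found in the RefSeq reference overlapped the reference gene of that name. Listed starts lay 1 base below the reference start in 7654 genes and were equal to it in 579, so they were read as counted from 0 and are printed counted from 1, in mm10. Another 4294 lines held only tabs and were left out.

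Transcript FPKM was summed per gene symbol, which gave 16709 symbols. A pseudocount of 1 was added, and the log2 ratio of Nutlin-3a over DMSO was taken. Log2 ratios below are on this log2(FPKM + 1) scale, which understates the ratio of weakly expressed genes, while folds are plain ratios of the authors' FPKM. Genes entered the comparison with a mean FPKM of at least 1 over both groups and a value above 0 in each. A gene was called higher or lower in Nutlin-3a at a 2-fold or larger difference on the log2(FPKM + 1) scale. Counts of genes past or within 2-fold use this scale, so a gene with a plain fold over 2 can count as within. Genes listed at 0 in a group are given no fold, since a 0 in such a table can be a failed estimate. The planned tests across libraries, including a limma fit, its leave-one-out and blocked forms, and rotation and competitive gene set tests, need a value per library and were not run. The size limit took the place of a test threshold once the table had been seen, and so did the sum over transcripts in place of the transcript with the highest mean. No difference below was set against the spread between replicates, and no p-value was computed.

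A total of 23 gene lists were fixed before the data were examined. They covered p53 targets, G2 and mitosis, DNA replication, DNA repair, adipogenic regulators, mature adipocyte markers, adipogenesis inhibitors, fatty acid oxidation, glycolysis, cholesterol synthesis, senescence-associated secreted factors, extracellular matrix and fibroblast genes, interferon-stimulated genes, the integrated stress response, endoplasmic reticulum chaperones, NRF2 targets, autophagy and lysosome genes, and housekeeping genes. Markers of macrophages, muscle, bone and cartilage, epithelium and endothelium stood for other cell types. The median log2 ratio of a list was placed as a percentile among 10000 random lists of the same size, drawn within 20 classes of mean FPKM. That percentile describes these group values and is not a p-value. Genes were named by a rule also fixed beforehand: Trp53 and 5 of its regulators and targets in any case; the 10 genes with the largest ratio in each direction with at least 5 FPKM in the higher group, without predicted genes and pseudogenes; and up to 4 members per list with the largest absolute ratio past the limit. Some genes that the rule or a list would name are not reported here. Other genes are named as examples of a list or where chosen after their values were seen.

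Gene types, transcript lengths and GC content came from GENCODE release M21, matched by symbol. GC content was found for 9935 of the genes compared (96.2%). Alternatives were other pseudocounts, filters, scalings, fold limits, a correction for GC content and other ways to combine transcripts. The depth of each library is unknown from the files. The most common low value of FPKM scaled by transcript length was 0.0515 FPKM × kb in Nutlin-3a (1354 genes) and 0.046 in DMSO (920 genes). It was read as the value of 1 fragment, which was not checked, so the depth behind the columns is not settled by it. The calls were tested on simulated data for this comparison, with 10331 genes and noise with an SD of 0.4 on the log2 scale, an assumed value. Of 100 genes set 8-fold apart 97 were recovered, of 100 set 2-fold apart 35, and 64 of 10131 unchanged genes were called. The log2 ratios of the data spread more widely, with 2.5th and 97.5th percentiles of -1.359 and 1.482. How much of that spread is noise is unknown, so these rates hold only for the assumed SD. Lists of 20 genes shifted by 0.5 on the log2 scale fell outside the middle 95% of random lists in 50 of 50 cases. Unshifted lists did so in 1 of 50, and smaller shifts were not simulated. The noise in these lists had the same assumed SD and was drawn independently for each gene. Their rates therefore do not cover the wider spread of the data or lists whose members vary together. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.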

Results

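RNA sequencing measured transcript levels in 3T3-L1 cells, a mouse fibroblast-like line that can be differentiated into adipocytes and was studied here as preadipocytes. The cells received 25 µM Nutlin-3a for 24 h or the vehicle DMSO. Nutlin-3a is a small molecule that occupies the p53-binding pocket of MDM2 and so keeps this ubiquitin ligase away from p53. Each group had 2 biological replicates, 4 libraries in all. The comparison asks which transcripts differ in preadipocytes once p53 is released in this way. The authors' table gave 1 FPKM value per transcript and group, with no value per library. The values therefore carry no replicate error, and higher and lower below describe the size of the ratio between the authors' group values. Summed over all transcripts, FPKM was 967341 in Nutlin-3a and 980491 in DMSO. The 20 most abundant genes held 27.4% and 27.3% of these sums. The 95 genes with the Rpl or Rps stem of ribosomal proteins, which some kinase genes share, held 45.9% and 44.8%.

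The p53 targets Cdkn1a, Ccng1 and Ppm1d were more than 4-fold higher in Nutlin-3a, whereas the p53 gene itself stayed within 2-fold. Cdkn1a, which encodes the cyclin-dependent kinase inhibitor p21, was listed at 386 FPKM in Nutlin-3a and 35.2 FPKM in DMSO, a 10.98-fold higher value. Ccng1, the cyclin G1 gene, was 8.96-fold higher (200 against 22.3 FPKM), and Ppm1d, a phosphatase that dephosphorylates p53, was 4.31-fold higher (17.9 against 4.14 FPKM). Trp53, the gene of p53, was listed at 63.1 FPKM in Nutlin-3a and 54.5 FPKM in DMSO, a log2 ratio of 0.21. Mdm4, a relative of Mdm2 that also binds p53, had 9.78 against 6.18 FPKM, a log2 ratio of 0.59. That sum joins transcripts that went opposite ways, such as 6.70 against 0 FPKM and 0.0098 against 5.67 FPKM.

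Mdm2, the target of the compound and itself a p53 target, was listed at 0 in Nutlin-3a and at 773 FPKM in DMSO. Both of its listed transcripts had this form, with 759 and 13.3 FPKM in DMSO. No fold is given for Mdm2, because a 0 in this table can be a failed estimate. 3T3-L1 cells are known to carry an amplified Mdm2 locus, which was not examined here. In DMSO the gene ranked 178 of 16709 symbols by FPKM. Among these genes, Cdkn1a lies on chromosome 17 from 29090986 to 29100722, Ccng1 on chromosome 11 from 40748552 to 40755286 and Ppm1d on chromosome 11 from 85311254 to 85347071. Trp53 lies on chromosome 11 from 69580359 to 69591873, Mdm2 on chromosome 10 from 117688875 to 117710758 and Mdm4 on chromosome 1 from 132986105 to 133030587 (all mm10, whole gene models as listed).

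Of 10331 genes compared, 684 (6.62%) were at least 2-fold higher in Nutlin-3a and 634 (6.14%) at least 2-fold lower, while 9013 lay within 2-fold. The balance moved with scaling and filter, to 598 higher and 714 lower after quantile normalization, and 391 and 466 with a mean FPKM of at least 5. Over the 9935 genes with a GC content it was 652 higher and 615 lower, and 707 and 487 after a correction for GC content. The median log2 ratio was 0.07, with quartiles of -0.33 and 0.44. Across genes, which are not independent replicates, log2(FPKM + 1) of both groups had a Pearson r of 0.945. Ratios also moved with GC content, with a Spearman rho of -0.228 across 9935 genes. With genes split into 8 classes of equal size by GC content, the median log2 ratio was 0.26 in the class of lowest GC and -0.21 in the class of highest GC. Another 43 genes past the minimum mean were listed at 0 in DMSO and 6 were listed at 0 in Nutlin-3a.

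**Figure D1:**
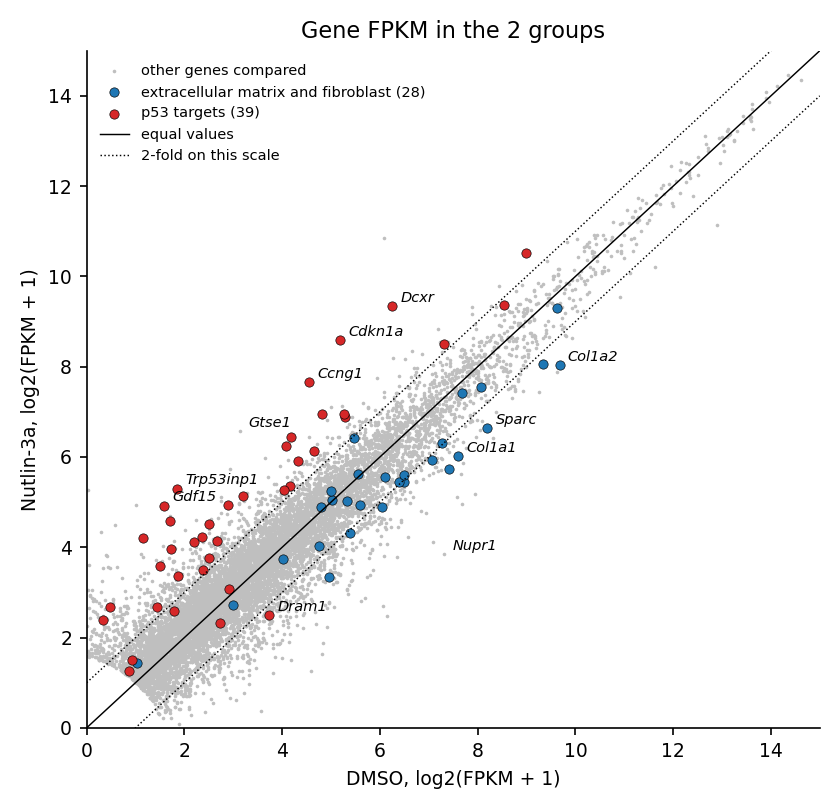
Gene FPKM in both groups on a log2(FPKM + 1) scale, DMSO on the x axis and Nutlin-3a on the y axis, each point a gene compared. Of 39 p53 targets (red) 32 lie above the upper dotted 2-fold line, and of 28 extracellular matrix and fibroblast genes (blue) 10 lie below the lower one.

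The genes highest in Nutlin-3a relative to DMSO included p53 targets and several genes that were nearly silent in DMSO. Trp53inp1, a p53-induced stress protein gene, had 38.4 against 2.62 FPKM, and Gdf15, a secreted stress-response cytokine, had 29.3 against 2.0 FPKM. Gtse1, a microtubule-associated regulator of p53, was 12.1-fold higher (94.2 against 7.78 FPKM). Genes with little signal in DMSO were Ces2e, a carboxylesterase gene (37.5 against 0.0148 FPKM), Oxt, the oxytocin precursor gene (19.3 against 0.234 FPKM), and Tnnc2, a troponin C gene of fast skeletal muscle (21.6 against 0.503 FPKM). Svop, a synaptic vesicle protein gene, had 11.2 against 0.0341 FPKM, and Spx, the gene of the peptide hormone spexin, had 10.6 against 0.253 FPKM. Zeros were not alike in both groups. Of 65 olfactory and vomeronasal receptor genes, all listed above 0 in at least 1 group, 72.3% were at 0 in DMSO and 7.7% in Nutlin-3a. Values near 0 are therefore uncertain. Lars2, the mitochondrial leucyl-tRNA synthetase gene, was 27.5-fold higher (1849 against 67.2 FPKM). The mouse Lars2 transcript carries a stretch resembling large-subunit ribosomal RNA, so its value is uncertain. The ribosomal RNA precursor Rn45s, chosen after its values were seen, was listed at 458 FPKM in Nutlin-3a and 249 FPKM in DMSO. Ces2e belongs to a cluster of closely related carboxylesterase genes that can share reads, which makes its value uncertain too.

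Among the genes lowest in Nutlin-3a relative to DMSO, S100a16, an S100 calcium-binding protein gene, was 15.4-fold lower (4.56 against 70.0 FPKM). Nupr1, a stress-induced chromatin regulator, was 11.8-fold lower (13.4 against 158 FPKM). Nnmt, which methylates nicotinamide, was 12.0-fold lower (5.49 against 65.6 FPKM), and Gamt, an enzyme of creatine synthesis, was 12.8-fold lower (2.12 against 27.1 FPKM). Ubd, a ubiquitin-like modifier gene, had 1.38 against 23.0 FPKM, and Aldh3b1, an aldehyde dehydrogenase gene, had 2.69 against 27.7 FPKM. Crip1, a LIM domain protein gene, had 16.4 against 134.8 FPKM, and Rarres2, which encodes the adipokine chemerin, had 5.996 against 47.9 FPKM. Tk1, the cytosolic thymidine kinase gene, was 8.11-fold lower (6.30 against 51.1 FPKM), and Zfp467, a zinc finger gene, had 0.290 against 10.9 FPKM. The listed gene model of Gamt spans neighbouring genes, from 79697305 to 80369637 on chromosome 10 (mm10), so its value is uncertain. Whether gene models of other genes named here or below also reach over neighbours was not checked. Examples are Tk1, listed from 117815519 to 117839908 on chromosome 11, and Rarres2, from 48554799 to 48572670 on chromosome 6.

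The fixed list of p53 targets was higher as a group. Of 39 members compared, 32 were at least 2-fold higher on the log2(FPKM + 1) scale, 6 lay within 2-fold on it and 1 was lower. Their median log2 ratio of 1.69 lay above those of all 10000 random lists matched on expression, whose middle 95% ran from -0.18 to 0.26. Beside Cdkn1a, Ccng1, Trp53inp1 and Gdf15, the higher members included the apoptosis genes Bbc3 (16.5 against 3.56 FPKM), Fas (69.7 against 24.0 FPKM) and Tnfrsf10b (34.0 against 8.22 FPKM). They also included the antiproliferative gene Btg2 (22.9 against 2.28 FPKM), the death receptor gene Eda2r (17.5 against 1.23 FPKM) and Dcxr, a dicarbonyl and xylulose reductase gene (646 against 75.5 FPKM). Bax, a pro-apoptotic member of the BCL2 family, stayed within the limit at 658 against 370 FPKM. Sesn1, a sestrin gene, was also within it at 3.97 against 5.597 FPKM. So were Plk3 and Tigar, with plain folds of 2.02 and 2.03. Dram1, a lysosomal membrane protein gene linked to autophagy, was the member listed lower, at 4.68 against 12.3 FPKM. Mdm2 was left out of these counts because it was listed at 0 in Nutlin-3a, 4 members were under the minimum mean, and Pmaip1 was not analysed here.

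**Figure D2:**
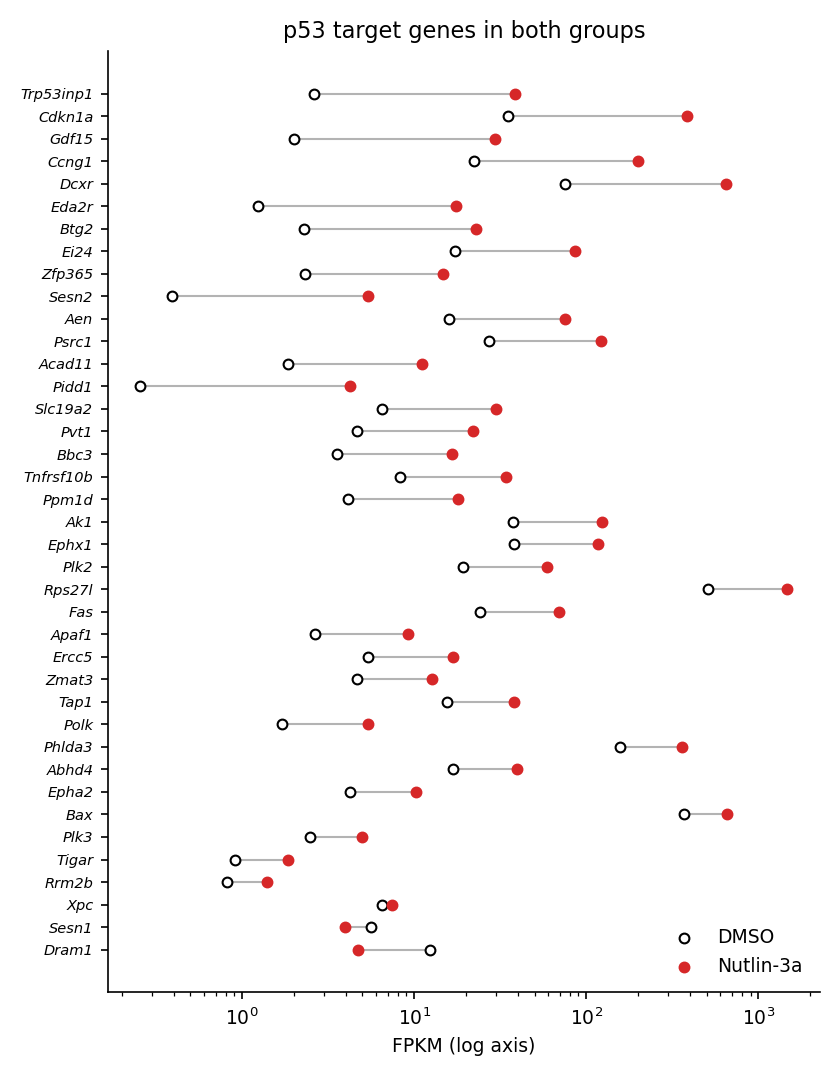
FPKM of the 39 p53 targets compared, on a log axis, with DMSO as open circles and Nutlin-3a as red circles joined by a line per gene. Cdkn1a runs from 35.2 to 386 FPKM, and Sesn1 and Dram1 are the members with the red circle on the left.

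Genes of mitosis lay modestly lower, and most genes of DNA replication and repair lay within 2-fold. Of 37 genes of G2 and mitosis, 4 were at least 2-fold lower and none was at least 2-fold higher. These 4 were Ccnb2 (21.7 against 50.7 FPKM) and Ccna2 (11.7 against 25.3 FPKM), both cyclins, Foxm1 (7.80 against 17.4 FPKM), a transcription factor of mitotic genes, and Racgap1 (20.9 against 46.1 FPKM), which acts in cytokinesis. Birc5, the survivin gene, had 119.6 against 228 FPKM and stayed within the limit, as did Mki67, a proliferation marker (9.61 against 14.7 FPKM), and Cdk1 (49.5 against 55.4 FPKM). The list's median log2 ratio of -0.22 lay at percentile 0.88 of matched random lists, and it moved inside their middle 95% (percentile 4.08) when the transcript with the highest mean stood for each gene. Of 38 DNA replication genes, 3 were lower, namely Tk1, Uhrf1 (7.51 against 18.5 FPKM) and the DNA ligase gene Lig1 (17.3 against 36.9 FPKM). Rrm2, a ribonucleotide reductase subunit gene, was 2.95-fold higher (31.5 against 10.7 FPKM), and Pcna, the sliding clamp gene, had 203 against 175 FPKM. After a correction for GC content, Foxm1 (-0.95) and Lig1 (-0.90) lay inside the limit. The median of the replication list was -0.16 (percentile 4.55), inside the middle 95%, and at percentile 2.43, outside it, without a filter on low values. None of 16 genes of homologous recombination and the Fanconi pathway passed the limit, with Brca1 at 3.18 against 2.64 FPKM (median 0.01, percentile 28.75).

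**Figure D3:**
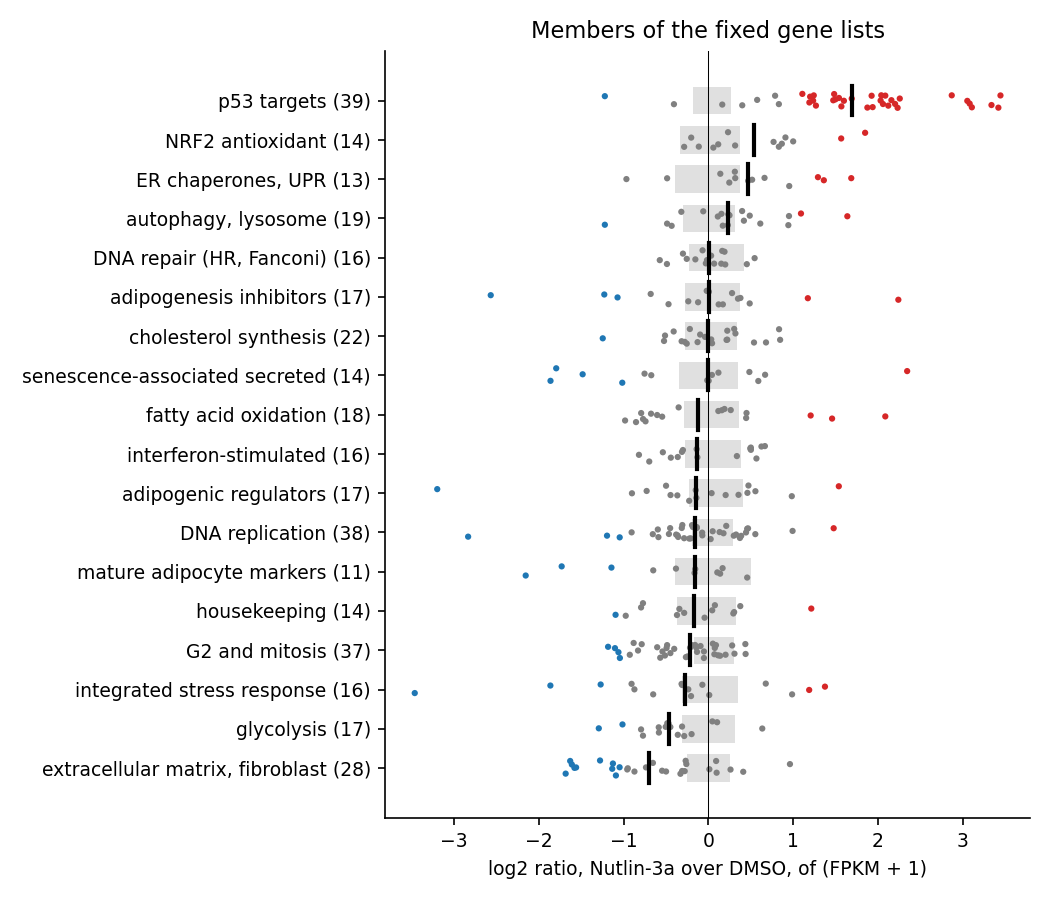
Log2 ratios of Nutlin-3a over DMSO for the members of 18 fixed lists, each point a gene (red at least 2-fold higher, blue at least 2-fold lower), with the number compared in brackets. Black bars are list medians and grey bands the middle 95% of medians of matched random lists, and the p53 bar at 1.69 and the matrix bar at -0.70 lie farthest from their bands.

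Most regulators of adipogenesis that were compared lay within the 2-fold limit, while a few markers of mature adipocytes were lower in Nutlin-3a. Pparg, the central adipogenic transcription factor, had 11.3 against 16.4 FPKM, Cebpa had 4.03 against 2.43 FPKM and Cebpb had 380 against 422 FPKM, all within 2-fold. Of 17 adipogenic regulators, Klf15 was the member listed higher (2.14 against 0.0825 FPKM) and Zfp467 the member listed lower. The list median was -0.14 (percentile 7.75). Of 11 mature adipocyte markers compared, 3 were lower: the fatty acid carrier gene Fabp4 by 4.86-fold (8.65 against 42.0 FPKM), the lipid droplet gene Plin4 by 3.92-fold (3.87 against 15.2 FPKM) and the lipoprotein lipase gene Lpl by 2.26-fold (24.1 against 54.5 FPKM). The list median of -0.16 over these 11 lay at percentile 15.17. Another 12 markers, among them Adipoq, Lep and Plin1, were under the minimum mean. All 12 had the higher value in Nutlin-3a, such as Adipoq with 0.840 against 0.0409 FPKM, though values near 0 are uncertain. Of 17 genes on the fixed list of adipogenesis inhibitors, Wnt6 (12.7 against 80.6 FPKM), Wnt10a (0.821 against 3.27 FPKM) and Tgfb1 (5.41 against 12.5 FPKM) were lower. Wnt10a lay just inside the limit after a correction for GC content (-0.98). Rb1, the retinoblastoma gene (8.70 against 1.05 FPKM), and Foxc2, a forkhead factor gene (19.8 against 8.24 FPKM), were higher. How members of this list, Rb1 among them, act on adipogenesis in these cells was not tested. Dlk1, a preadipocyte marker, had 623 against 513 FPKM, and the median of the inhibitor list was 0.01 (percentile 35.16).

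Glycolytic genes lay lower as a group. Of 17 compared, 14 had a log2 ratio below 0, and Tpi1, triosephosphate isomerase (398 against 978 FPKM), and Pfkm, a phosphofructokinase gene (15.1 against 31.5 FPKM), were at least 2-fold lower. Gapdh (602 against 1045 FPKM), Pgk1 (488 against 835 FPKM) and Ldha (447 against 671 FPKM) lay lower within the limit. The list median of -0.47 was at percentile 0.33 of matched random lists. Pfkm lay just inside the limit after upper-quartile scaling (-0.98) and after a correction for GC content (-0.87). Fatty acid oxidation genes went both ways, with 3 of 18 higher and none lower by the limit. Those higher were Acad11, an acyl-CoA dehydrogenase gene also on the p53 list (11.03 against 1.83 FPKM), Lpin1, the lipin 1 gene (3.52 against 0.645 FPKM), and Cpt1c, a carnitine palmitoyltransferase gene (33.3 against 13.9 FPKM), with a log2 ratio of 0.80 when its transcript with the highest mean stood for it. Acadm, the medium-chain dehydrogenase gene, had 15.6 against 31.9 FPKM, and the list median was -0.12 (percentile 16.44). With a mean FPKM of at least 5 it was -0.45 over 16 genes (percentile 0.58), outside the middle 95%. Of 22 cholesterol synthesis genes Pmvk, phosphomevalonate kinase, was the member past the limit (13.0 against 32.2 FPKM), and the list median was 0.00 (percentile 36.96).

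Extracellular matrix and fibroblast genes were the group with the lowest median. Of 28 compared, 10 were at least 2-fold lower and none was at least 2-fold higher. The fibrillar collagen genes Col3a1 (52.0 against 169.5 FPKM), Col1a2 (263 against 817 FPKM) and Col1a1 (63.9 against 193 FPKM) were 3.26-fold, 3.11-fold and 3.02-fold lower. Pdgfra, a growth factor receptor gene of mesenchymal cells, was 3.28-fold lower (9.14 against 30.0 FPKM), and the matrix protein genes Sparc (98.3 against 292 FPKM), Postn (60.0 against 132 FPKM) and Dcn (28.9 against 64.6 FPKM) were lower as well. Fn1, the fibronectin gene, had 171 against 205 FPKM, and the basement membrane collagen gene Col4a1 had 48.6 against 45.6 FPKM. The list median of -0.70 lay below those of all 10000 matched random lists. Over the 26 members with a GC content it was -0.81 with 10 lower, and -0.73 with 8 lower after a correction for GC content. Among senescence-associated secreted factors, 1 of 14 was higher and 4 were lower. Cxcl1, a neutrophil chemokine gene, was 5.43-fold higher (62.4 against 11.5 FPKM). Igfbp4 (14.6 against 55.9 FPKM), Igfbp3 (9.43 against 35.2 FPKM), the matrix protease gene Mmp3 (10.3 against 30.5 FPKM) and the chemokine gene Ccl5 (9.59 against 20.4 FPKM) were lower. Ccl5 lay just inside the limit after upper-quartile scaling (-0.99) and after a correction for GC content (-0.91). That list's median was -0.01 (percentile 42.02).

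NRF2 antioxidant genes lay higher, with a median log2 ratio of 0.54 over 14 genes (percentile 99.81). Gclc, a subunit of the enzyme that starts glutathione synthesis (7.46 against 1.35 FPKM), and Txnrd1, thioredoxin reductase (41.1 against 13.2 FPKM), passed the limit, and the heme oxygenase gene Hmox1 (221 against 110 FPKM) lay just under it. Endoplasmic reticulum chaperone genes also lay higher, with a median of 0.47 over 13 genes (percentile 99.46). Dnajb9 (11.7 against 2.94 FPKM), Sdf2l1 (37.1 against 13.8 FPKM) and Hyou1 (12.9 against 4.70 FPKM) passed the limit, while Hspa5, the main chaperone gene of this compartment, had 278 against 234 FPKM. The integrated stress response went both ways, with 3 of 16 lower and 2 higher. Nupr1, Trib3 (8.39 against 33.2 FPKM) and Chac1 (1.53 against 5.12 FPKM) were lower, Atf3 (2.53 against 0.363 FPKM) and Ddit4 (58.7 against 25.2 FPKM) were higher, and the median was -0.27 (percentile 4.05). After a correction for GC content it was -0.28 (percentile 2.18), outside the middle 95%. Of 19 autophagy and lysosome genes, the autophagy kinase gene Ulk1 (23.1 against 6.75 FPKM) and Map1lc3b (223 against 104 FPKM) were higher and Dram1 lower, with a median of 0.23 (percentile 92.18). None of 16 interferon-stimulated genes passed the limit, with Isg15 at 105 against 130 FPKM and a median of -0.14 (percentile 10.3).

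Markers of other cell types were weak in both groups. Of 3 macrophage markers compared, Aif1 was lower (0.642 against 3.13 FPKM), Cd68 had 6.52 against 2.91 FPKM and Cd14 had 3.03 against 4.48 FPKM, while Ptprc, the pan-leukocyte marker, was at 0.0618 FPKM in Nutlin-3a and listed at 0 in DMSO, values as uncertain as the others near 0. Of 3 muscle markers, Acta1, skeletal actin, was higher (1.74 against 0.368 FPKM, inside the limit at 0.80 after quantile normalization), Des had 4.15 against 4.90 FPKM and Tnnt3, a troponin T gene, had 1.76 against 3.43 FPKM. Eng, an endothelial marker that mesenchymal cells also express, was 4.21-fold higher (6.52 against 1.55 FPKM). Runx2, a bone regulator, had 8.97 against 4.23 FPKM, and the epithelial keratin gene Krt19 had 1.42 against 1.39 FPKM. The other markers found were under the minimum mean. Most of them had a higher value in Nutlin-3a, among them Col2a1 (1.72 FPKM, listed at 0 in DMSO) and Pecam1 (1.57 against 0.026 FPKM). Alpl, Sox5, Phex and Tek went the other way. Of 14 housekeeping genes, Hprt was higher (109.6 against 46.7 FPKM), and the list had a median of -0.17 (percentile 16.59). Hprt had a log2 ratio of 0.9965 after a correction for GC content, just inside the limit. Actb had 1515 against 1848 FPKM and Tbp 10.2 against 8.07 FPKM.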

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

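The test on neighbouring genes had its limits set before its result was seen, and its interval and all other tests in this part were chosen after the values had been seen. Signal appeared in Nutlin-3a in genes outside the comparison. Olfactory and vomeronasal receptor genes, which serve sensory neurons, had a median of 0.0504 FPKM in Nutlin-3a and of 0 in DMSO over 65 genes. Of these, 47 (72.3%) were listed at 0 in DMSO and 5 (7.7%) in Nutlin-3a. No transcript was listed at 0 in both groups, so the shares and medians in this part leave out genes without signal in either group. The 6329 genes under the minimum mean had a median of 0.118 FPKM in Nutlin-3a and 0.032 FPKM in DMSO, and 72.1% of those with unequal values were higher in Nutlin-3a. In all, 2346 genes were listed at 0 in DMSO and 466 in Nutlin-3a. At a higher level, 33 genes had at least 5 FPKM in Nutlin-3a and under 0.5 FPKM in DMSO, against 3 the other way (Mdm2, 1190005I06Rik and Zfp467). The 33 included Ces2e, Oxt, Svop and Spx, the neuronal stathmin gene Stmn4 (8.55 against 0.244 FPKM), the costimulatory gene Cd80 (6.28 against 0.110 FPKM), the kisspeptin gene Kiss1 (6.22 FPKM, listed at 0 in DMSO) and the p53 target Sesn2 (5.4 against 0.392 FPKM).

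Greater depth in Nutlin-3a stays open for the shorter list of zeros. The most common low value, read as 1 fragment, was 1.12 times that in DMSO, and greater depth needs a smaller value. That reading was not checked, so the ratio cannot decide the question. For the 33 genes greater depth is argued against, because FPKM is already scaled to the mapped fragments. Low values were also resolved in DMSO, with a median of 0.032 FPKM over the 6329 genes under the minimum mean. Less depth there would thus not bring 5 FPKM under 0.5 FPKM. The tables argue against a uniform background of reads over silent genes as the source of the 33 genes, as the receptor median in Nutlin-3a was 0.77% of their median of 6.54 FPKM. For the shorter list of zeros such a background stays open, because the difference of 64.6 percentage points in receptor genes at 0 is part of that same observation, and so does quantification of the groups with unlike settings, which was not tested. Reads of a nearby gene stay open too. Of the 33, 4 (4930415O20Rik, Gzmm, Pcdhga10 and Wfdc18) had a gene at least 2-fold higher in Nutlin-3a within 5 kb. That is 12.1%, against 2.8% of 4890 genes under 0.5 FPKM in both groups. The 95% interval of 3.4 to 28.2% reached past the limit of 25% set for ruling such reads out. The listed gene model of Pcdhga10 runs from 36930285 to 37841872 on chromosome 18 (mm10), and genes inside this span counted as near. Whether the outcome holds without Pcdhga10 was not tested. An effect of the treatment on the 33 genes stays open and untested, as the table used here gives 1 value per group.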

How the results depend on the processing

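The fold limits, the correction for GC content, the handling of zeros, the restrictions to protein-coding genes and to genes with a GC content and the use of every transcript were chosen after seeing the data; pseudocounts, filters, scalings and the transcript with the highest mean were set before. The number of genes at least 2-fold higher moved from 684 to 1038 with a pseudocount of 0.01, to 391 with a mean FPKM of at least 5 and to 1099 with every transcript counted. More genes were higher than lower with the settings chosen, but fewer after quantile normalization (598 against 714) and with a mean of at least 5 (391 against 466). Over the 9935 genes with a GC content it was 652 against 615, and 707 against 487 after the correction. With limits of 1.5-fold and 4-fold the number higher was 1839 and 91, and the number lower moved from 634 to 1566 and 63; these follow from the limits themselves. Of 143 list medians under alternatives that could alter them, 139 stayed inside or outside the middle 95% of random lists as before, though some medians near 0 changed sign inside it. An exception was DNA replication without a filter, now just outside the middle 95%. Its median stayed at -0.1609, while the lower edge of the random lists moved from -0.1959 to -0.16. Fatty acid oxidation with a mean of at least 5 (-0.45) and the integrated stress response after the correction for GC content (-0.28) also came to lie outside. G2 and mitosis with the transcript of highest mean (-0.16) came to lie inside. The cause of these changes was not tested. Filters cannot alter the ratio of a single gene, so 266 of the 678 log2 ratios of 69 genes named by rule were fixed in advance. Of the other 412, 30 moved by over 1.5-fold, 29 of them with smaller pseudocounts and 1, of Zfp467, with the transcript of highest mean. A smaller pseudocount cannot turn a ratio or bring it inside the limit; of the 274 under scalings, the transcript of highest mean and the correction for GC content, none changed sign past the limit and 8 fell inside the limit (Pfkm in 2 settings, Foxm1, Lig1, Wnt10a, Hprt, Cpt1c and Acta1). Among the other list members called, Ccl5 (upper-quartile scaling and the correction for GC content) and Col6a2 and Col6a3 (that correction) fell inside it. Scalings moved the median of all genes by 0.03 (upper quartile) and -0.06 (quantile). No paired analysis was possible because the table holds 1 value per group. Fits leaving out a library, other tests and other gene set tests were not run for the same reason. Depth per library is unknown, and of simulated genes set 2-fold apart 35 of 100 were recovered at the assumed noise.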

Other observations

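The scan of gene families, the genes beside Mdm2, the tests on Mdm2 and the correction for GC content were chosen after the gene values had been seen. All 112 families of symbols with a shared stem and at least 10 genes compared were scanned, and 12 medians lay outside the middle 95% of matched random lists. By chance 5.6 would be expected if the members of a family varied independently, which was not checked. Genes with the stem Cox, mainly subunits and assembly factors of cytochrome c oxidase, had a median log2 ratio of 0.40 over 21 genes (percentile 99.82). Among them Cox4i1 had 1933 FPKM in Nutlin-3a and 1386 FPKM in DMSO, Cox5b had 835 against 565 FPKM, and Cox20 was lower at 31.9 against 80.03 FPKM. Genes of the Arl stem, small GTPases and their partners, had a median of 0.45 over 19 genes, 4 of them at least 2-fold higher and 1 lower. Arl1 had 50.2 against 18.0 FPKM, Arl8a had 40.0 against 17.8 FPKM, and Arl2 was lower at 127 against 331 FPKM. Dnajc co-chaperone genes had a median of 0.42 over 22 genes, 3 of them higher by the limit and 1 lower. Dnajc9 had 112.5 against 29.2 FPKM, Dnajc3 had 11.5 against 4.58 FPKM, and Dnajc17 was lower at 5.01 against 11.8 FPKM.

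Families on the lower side included guanine nucleotide exchange factor genes of the Arhgef stem, with a median of -0.69 over 14 genes. Arhgef25 had 43.5 against 105.8 FPKM and Arhgef2 had 11.8 against 22.9 FPKM. Collagen genes had a median of -0.66 over 23 genes, with 7 lower by the limit and 2 higher, Col9a3 (5.11 against 1.32 FPKM) and Col20a1 (7.03 against 2.52 FPKM), neither on the matrix list. Fkbp prolyl isomerase genes had a median of -0.57 over 13 genes, with Fkbp11 at 33.5 against 189.7 FPKM and Fkbp10 at 52.8 against 96.5 FPKM. Annexin genes had a median of -0.50 over 10 genes, with Anxa6 lower (38.7 against 86.4 FPKM) and Anxa8 higher (52.6 against 6.68 FPKM) by the limit. Of the 12 families, 11 stayed outside the middle 95% after upper-quartile scaling, 9 after quantile normalization and 7 after the correction for GC content. The Dnajc median fell inside it after that correction (0.32), whereas Cox (0.31), Arl (0.39), Arhgef (-0.58), collagen (-0.45), Fkbp (-0.61) and the annexins (-0.53) stayed outside. No explanation of these family medians was tested.

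Slc35e3, a solute carrier gene next to Mdm2 on chromosome 10, was listed at 417 FPKM in Nutlin-3a and 317 FPKM in DMSO, ranks 258 and 351 of all symbols. Nup107, a nuclear pore gene, had 55.1 against 14.4 FPKM, Cpm, a carboxypeptidase gene, had 3.68 against 0.313 FPKM, and Rap1b, a small GTPase gene, had 56.8 against 38.1 FPKM, so all 4 other genes listed within 150 kb had higher values in Nutlin-3a.

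For Mdm2 at 0 in Nutlin-3a and 773 FPKM in DMSO, exchanged group columns are argued against, because 97.0% of the other p53 targets past the 2-fold limit were higher in Nutlin-3a. A failed estimate in the table may be the source, since 3T3-L1 cells are known to carry an amplified Mdm2 locus and a locus with too many fragments can be given as 0. That 1 other protein-coding gene (1190005I06Rik) was at 0 in a group and at 10 FPKM or more in the other decides nothing. Of the 11 genes of any type with that form, 9 were small nucleolar RNA or microRNA genes. A failed estimate and a loss of the transcript under treatment cannot be told apart from the table used here, which gives 1 value per group.

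Ratios moved with GC content, and a GC content trend between the group values could have shifted whole lists. After the correction the medians were 1.81 for p53 targets, -0.73 for matrix genes and -0.39 for glycolytic genes, against 1.69, -0.81 and -0.47 over the same genes before it, each still outside the middle 95% of matched random lists, so the trend is argued against as the whole cause of these medians. An effect of the treatment remains a hypothesis for all 3, found and tested on the same group values. The source of the GC trend itself was not tested.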
